A study of Homo sapiens with 12 samples.

How the data were processed

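Gene expression was measured in Caco-2 cells, a human colon carcinoma line that forms a polarised, enterocyte-like monolayer after confluence. Post-confluent dishes were incubated for 2 h with medium alone, with S1400, with EAV9, or with recombinant flagellin, the protein subunit of the bacterial flagellum. Per the labels, 100000000 bacteria or 100 ng of flagellin were added; no volume is given beside the 100 ng in the sources used here. The study's design names a flagellated and an aflagellated Salmonella enteritidis, while the sample labels give only the strain names. S1400 is taken here as the flagellated strain and EAV9 as the aflagellated one, from the order in which the design lists the treatments and from general knowledge of the strains; no label ties either name to flagellation. Poly(A) RNA was labelled and hybridised to Affymetrix Human Genome U133 Plus 2.0 arrays, per the labels. The 4 groups held 3 arrays each, 12 in all, from 3 independent experiments.

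The deposited values are log2 signals, 1 per probe set and array. GCOS 1.2 and GCRMA are named in the submitters' processing notes, with no order or role; the GCRMA version is not given in the sources used here. GCRMA subtracts background by probe sequence, normalises between arrays and summarises each probe set. That the scale is log2 was read from the values, whose highest lay between 16.3 and 16.6 on each array, the top of a 16-bit scanner. The authors' values for 25676 of 54675 probe sets (47.0%) had no more than 3 significant digits on all 12 arrays, and the others had more; 4357 of the genes tested (40.0%) rest on such values. Array medians lay between 3.00 and 3.12 log2. Pairs of arrays correlated at 0.977 to 0.996 and 0 pairs were identical. No scanner intensities and no detection calls were used here, so the number of arrays limits the precision.

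The platform annotation gave 1 gene symbol for 41091 probe sets, several for 1801 and none for 11721; 62 were array controls. Symbols were updated through the gene number against a RefSeq table of assembly GRCh38.p14, which held 41037 of the probe sets with 1 symbol. No genome build is named for the array, so no coordinates are given. Probe sets with several symbols or none were left out of the gene analysis and were counted apart. Each of 19775 genes was represented by its probe set with the highest mean over the 12 arrays. The 10904 genes with a log2 value above 4 on at least 3 arrays were tested. Probe sets of the same gene changed in opposite directions, the opposing one at an unadjusted p under 0.05, for 4 genes that the naming rule reached: EGR1, BCL2L11, SREBF2 and LTB.

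Group means of all 12 arrays were fitted together in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, without trend or robust), so that the 4 groups share one estimate of the spread. The 6 pairwise comparisons and an F test over the 4 groups were read from this fit. Calls are at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. Errors beside log2 changes are the standard errors of that fit (n = 3 arrays per group); errors beside group levels are standard deviations. A permutation of 3 arrays against 3 cannot give a two-sided p below 0.1, so no single gene was tested that way. A gene whose 3 values in a group all lay at or below 4 is called dim there. Its fold is given as a lower bound, the brighter group's mean against 4, and no fold is given where both groups were dim. Where a named gene's group mean lay below 4 although 1 array exceeded it, the change is also or only given with values below 4 set to 4. The floor of 4 is a choice and not a detection limit.

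The replicate numbers were checked for pairing through the correlation of deviations from group means. The 18 pairs of arrays with the same number in different groups correlated at 0.135 to 0.763 (median 0.616), and the 36 pairs with different numbers at −0.64 to 0.357 (median −0.36). The numbers therefore pair the arrays, as 3 independent experiments would. The fit without the number was kept as the main result, and counts with the replicate number as a block stand beside it where they differ by more than 1.5 times. Calls of single genes, and their loss when arrays are left out, refer to the fit without the number unless the block is named.

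The naming rule took, per comparison, the 12 largest rises and 8 largest falls among called genes whose 3 values in one group all lay on one side of the 3 in the other. It also took up to 4 members with the smallest p of each gene list described, and always CXCL8, CCL20, NFKBIA, TNFAIP3, TLR5, EGR1, FOS and JUN. A gene named in one comparison may be given in another. Of 19 gene lists with 473 entries, 434 entries had a named probe set and 325 were tested. The lists were chemokines and cytokines, NF-kB feedback and targets, immediate early genes, MAP kinase feedback, flagellin and microbe sensing, interferon-stimulated genes, epithelial antimicrobial defence, apoptosis regulators, heat shock proteins, unfolded protein and amino acid stress, oxidative stress and metallothioneins, hypoxia and glycolysis, sterol synthesis, cell cycle, enterocyte differentiation, tight and adherens junctions, and markers of other cell types (fibroblast and endothelial; goblet, Paneth and enteroendocrine; leukocyte). The 18 lists with at least 5 tested members were tested against the other genes with camera (preset correlation 0.01), with adjusted p over the 18 lists of a comparison. They were tested again with the correlation estimated from the data and with fry, which asks whether a list moves one way on balance. Among the lists that passed, the median, the mean and the test differed in sign only for apoptosis regulators in S1400 against EAV9. A list said to shift upward or downward does so relative to all other genes. The groups, the comparisons, the model, the naming rule, the lists and the alternatives were fixed before the data were examined, except for 3 alternatives named in the closing section.

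Overlaps of calls were set against the number for independent lists only between comparisons that share no array; other counts of genes called in 2 comparisons share the control or the flagellin arrays, which ties the calls together. Alternatives covered quantile normalisation and median centring on top of the deposited values, the filter on dim genes, the choice of probe set, the arrays in the fit, the replicate block, the variance model, array weights, a 2-fold minimum and each array left out in turn. The fit was tested on simulated data of 10904 genes, with each gene's mean over the 4 groups and independent noise. The pairing of the arrays was not simulated, so the rates that follow need not hold for paired arrays. For S1400 against EAV9 it recovered 4% of 50 changed genes at a log2 change of 0.5, 46% at 1, 86% at 1.5 and 88% at 2, with 5 unchanged genes among 117 called. For EAV9 against control, simulated with no change, 0 genes were called. RNA quality was read from the actin probe sets as the 3' minus the 5' log2 signal. It was 1.13 ± 0.45 in control, 0.97 ± 0.32 with S1400, 0.93 ± 0.21 with EAV9 and 0.87 ± 0.15 with flagellin (SD, n = 3), and was highest on control array 2 (1.6). The same difference for GAPDH was 0.13 ± 0.15, 0 ± 0, 0.07 ± 0.06 and 0.03 ± 0.06 in that order. It was also highest on control array 2 (0.3), and it was not used as a covariate.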

Results

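The data set holds 12 arrays of Caco-2 cells, 3 each of control cells, cells incubated with S1400, cells incubated with EAV9 and cells incubated with recombinant flagellin, all for 2 h. The design asks which part of the epithelial response to Salmonella enteritidis goes through flagellin, the ligand of the cell-surface receptor TLR5. Of 10904 genes tested, 1432 differed among the 4 groups (limma F test, adjusted p under 0.05), and 3384 did with the replicate block. TLR5 itself lay near the bottom of the scale in every group, with mean log2 levels of 2.07 to 2.08, and was not tested. Between 10630 and 10839 genes exceeded the log2 floor of 4 on each array.

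**Figure D1:**
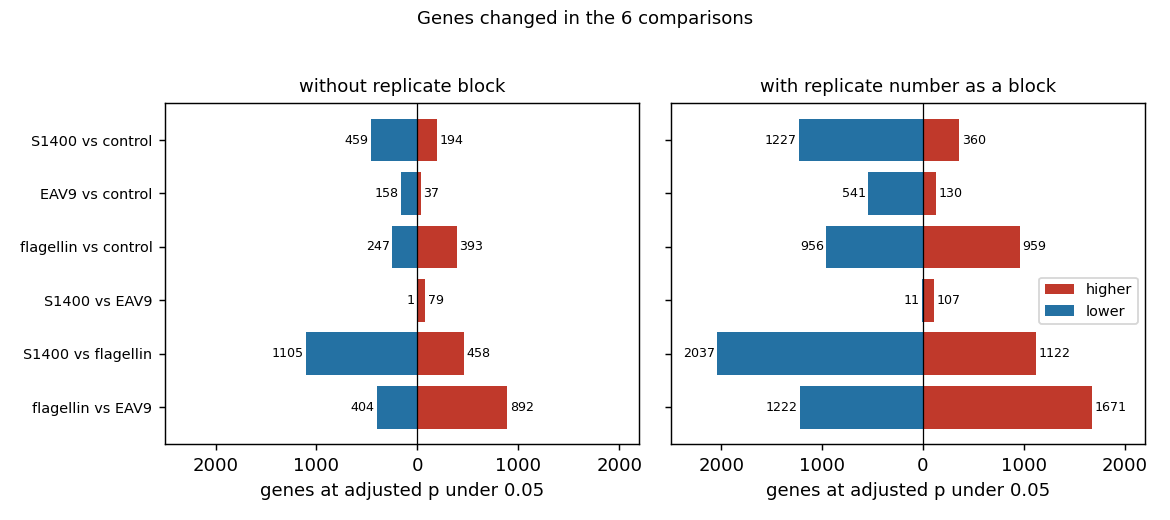
Number of genes higher or lower in each of the 6 pairwise comparisons at an adjusted p under 0.05, without (left) and with (right) the replicate number as a block. S1400 against EAV9 gave the fewest genes, 79 higher and 1 lower without the block, and S1400 against flagellin the most, 458 higher and 1105 lower.

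Incubation with S1400, compared with medium alone, raised neutrophil-attracting chemokines and the early feedback inhibitors of NF-kB. CXCL1 was at least 1009.6-fold higher (log2 change 10.96 ± 0.32) and CXCL8 rose by at least 7.06 on the log2 scale (8.36 ± 0.46), both dim in control cells. CCL20, which attracts dendritic cells and lymphocytes through CCR6, was at least 511-fold higher (10.21 ± 0.39). CXCL3 rose by a log2 of 9.14 ± 0.49 and CXCL2 by 7.67 ± 0.43. NFKBIA, the inhibitor that holds NF-kB in the cytoplasm, rose by 5.55 ± 0.31 (46.9-fold), and TNFAIP3, the ubiquitin-editing inhibitor A20, by 4.64 ± 0.21 (24.9-fold). The transcription factor IRF1 rose by 5.65 ± 0.30. MIR146A, the host transcript of a microRNA that dampens Toll-like receptor signalling, rose at least 45.9-fold, and NFKBID, an atypical inhibitor of the same family as NFKBIA, at least 14.6-fold. ACKR3, an atypical chemokine receptor, rose by 5.53 ± 0.59, the hydroxycarboxylic acid receptor HCAR3 at least 15.2-fold, and the stress gene GADD45B by 5.02 ± 0.21. ACKR3 exceeded 4 on 1 control array, and with values below 4 set to 4 its rise was 5.13.

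Parts of 4 lists rose with S1400. Of 17 chemokines and cytokines tested, from 28 with a named probe set, 8 rose and 0 fell (9 and 0 adjusted over the list alone), with list adjusted p = 5.82e-19. The filter left out members low in every group, such as CCL2 and CCL5. It kept others, such as CXCL8, only through the groups where they were high. This raises the share of the list that rose, here and in the comparisons below. Of 25 NF-kB feedback genes and targets, 10 rose and 0 fell (11 and 0 adjusted over the list alone; list adjusted p = 2.25e-15), IER3 among them (4.05 ± 0.31). Of 27 immediate early genes, 15 rose and 0 fell (19 and 1 adjusted over the list alone; list adjusted p = 2.6e-26). JUN rose by 3.29 ± 0.15, FOS by 3.08 ± 0.34 and ZFP36, which destabilises cytokine mRNA, by 3.56 ± 0.19, while EGR1 differed by 0.53 ± 0.44 (adjusted p = 0.669; with its probe sets averaged, 2.02 and adjusted p = 0.0124). Of 21 MAP kinase feedback genes, 10 rose and 1 fell (12 and 5 adjusted over the list alone; list adjusted p = 4.4e-09), including the phosphatase DUSP1 (2.71 ± 0.20) and PHLDA1 (2.55 ± 0.13). These 4 lists kept adjusted p of 0.00182, 0.00927, 0.00182 and 0.0156 with an estimated correlation, in the order given.

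The lists of hypoxia and glycolysis genes, of apoptosis regulators and of interferon-stimulated genes passed with S1400 at the preset correlation and not at an estimated one. By fry the first 2 passed (adjusted p = 0.0084 and 0.00548) and the interferon-stimulated list did not (0.262). Of 23 hypoxia and glycolysis genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone; list adjusted p = 0.000119, and adjusted p = 0.0655 with an estimated correlation), among them the mTOR inhibitor DDIT4 (4.04 ± 0.34) and the peptide hormone precursor ADM (3.97 ± 0.59). Of 23 apoptosis regulators, 3 rose and 0 fell, the same numbers adjusted over the list alone (list adjusted p = 0.0304; adjusted p = 0.0655 with an estimated correlation, 0.0626 with the replicate block and 0.192 without control replicate 2). They were PMAIP1 (4.07 ± 0.42) and BCL2L11 (2.36 ± 0.29), which promote apoptosis, and CFLAR (1.41 ± 0.15), which inhibits caspase-8. Probe sets of BCL2L11 ranged from −1.40 to 3.91, so its direction is uncertain. The interferon-stimulated list also passed, with 1 of 15 members risen, also adjusted over the list alone (ISG15, 2.12 ± 0.31; list adjusted p = 0.0336, adjusted p = 0.391 with an estimated correlation, 0.0673 when only genes with log2 above 6 on 3 arrays were tested, and 0.173 or 0.0834 without control replicate 1 or S1400 replicate 3). Of 23 junction genes, CLDN4 rose (1.55 ± 0.17) and CLDN2, a pore-forming claudin, fell (−1.15 ± 0.28), the same numbers adjusted over the list alone, and the list did not pass (adjusted p = 0.679).

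The largest falls with S1400 included C21orf91, which fell by 3.51 on the log2 scale, the zinc finger gene ZFP3 (−3.43 ± 0.32) and LCMT2, which takes part in tRNA modification (−3.19). ZNF606 was at least 7.89-fold lower, a call that ended without control replicate 2 or S1400 replicate 2 (adjusted p = 0.0546 and 0.055). ZC3H12C, of a family of RNA-degrading zinc finger proteins, changed by −3.16 ± 0.56, and RHOBTB1, BTBD7 and KIRREL1 by −3.08, −3.12 and −3.04. ZFP3, ZC3H12C and RHOBTB1 exceeded 4 on 1 S1400 array each, and with values below 4 set to 4 they changed by −3.34, −2.71 and −2.81.

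In total 653 genes changed with S1400, 194 higher and 459 lower, against 1874 at an unadjusted p under 0.05; 397 changed at least 2-fold. The groups did not overlap for 20.2% of all genes, where chance gives 10% for unpaired arrays. With the replicate block 1587 genes changed (360 higher, 1227 lower). Median centring gave 232 higher and 282 lower (45.1% higher, against 29.7%), while moving the median change of all genes from −0.06 to 0.06; without control replicate 2 or S1400 replicate 2 the count was 368 (207 lower) or 309. Without the 4 arrays numbered 2 it was 113, of which 71 were higher and 42 lower, so the falls no longer outnumbered the rises.

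EAV9, the strain taken as lacking flagella, left the chemokines near their control levels at 2 h. CXCL8 was dim on all control and EAV9 arrays, and CCL20, above 4 on 1 EAV9 array and dim in control cells, differed by 0.60 ± 0.39 (adjusted p = 0.715), or by 0.13 with values below 4 set to 4. NFKBIA differed by −0.03 ± 0.31 and TNFAIP3 by 0.34 ± 0.21 (adjusted p = 0.703). Of 17 chemokines and cytokines, and of 25 NF-kB feedback genes and targets, 0 rose and 0 fell, also adjusted over the list alone. The list adjusted p was 0.437 for each, and 0.981 for each by fry.

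Other genes did change with EAV9. TIPARP, an ADP-ribosyltransferase induced by the aryl hydrocarbon receptor, rose by 4.41 ± 0.23 (21.3-fold), and the histone gene H2BC21 by 4.21 ± 0.43 (18.5-fold). ADM rose by 3.46 ± 0.59, DDIT4 5.64-fold, and PDCD4, an inhibitor of translation, at least 3.76-fold. AMACR, a racemase of branched-chain fatty acid breakdown, rose by 2.99 ± 0.28, the kinase PIM1 by 2.06 ± 0.20, the arrestin-domain gene ARRDC3 by 2.57 ± 0.49, TCP11L2 by 3.04 ± 0.50, the exoribonuclease DIS3L2 by 2.34 ± 0.36, and NBEAL1 by 2.00 ± 0.32. The linker histone gene H1-3 rose at least 3.71-fold. Among falls, LCMT2 changed by −2.81 ± 0.13, ZC3H12C by −4.05 ± 0.56, ZFP3 by −3.15 ± 0.32 and C21orf91 by −2.94 ± 0.29. ZNF180 changed by −2.81, KIRREL1 by −2.72, the BMP co-receptor RGMB by −2.67 and the chemokine receptor-like CCRL2 by −2.43. With values below 4 set to 4, the changes of TCP11L2 (above 4 on 1 control array) and of ZC3H12C and CCRL2 (above 4 on 1 EAV9 array each) were 2.63, −2.87 and −2.22.

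Several of these calls with EAV9 ended when 1 array was left out. H1-3 lost its call in 9 of the 12 such fits (adjusted p of 0.0581 to 0.145), with the actin covariate (0.0549) and with no filter on dim genes (0.104). ARRDC3 lost it without control replicate 1 or 2 (0.0671 and 0.108), without EAV9 replicate 1, 2 or 3 (0.118, 0.08 and 0.0593) and with no filter (0.0748). ADM lost it without control replicate 1 or 2 (0.0568 and 0.078), without EAV9 replicate 1 or 3 (0.0782 and 0.067) and with no filter (0.0529). Without control replicate 2, TCP11L2, DIS3L2, NBEAL1 and RGMB had adjusted p of 0.079, 0.0549, 0.054 and 0.07. Without EAV9 replicate 1, DIS3L2 and NBEAL1 had 0.0636 and 0.0712, and without EAV9 replicate 3, TCP11L2, NBEAL1 and RGMB had 0.0602, 0.0574 and 0.0523. With only the 6 arrays of the 2 groups, TCP11L2, ARRDC3, H1-3, DIS3L2, NBEAL1, ZC3H12C, ZNF180, RGMB and CCRL2 were not called (adjusted p of 0.0542 to 0.142).

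Of 23 hypoxia and glycolysis genes, 2 rose with EAV9 and 0 fell (4 and 0 adjusted over the list alone; list adjusted p = 4.1e-05, and adjusted p = 0.209 with an estimated correlation). Of 27 immediate early genes 3 rose and 0 fell, namely SGK1, ZFP36 and HES1 (8 and 2 adjusted over the list alone; list adjusted p = 0.00197, and adjusted p = 0.402 with an estimated correlation). JUN differed by 0.58 ± 0.15 (adjusted p = 0.082, and 0.0454 with the replicate block). The enterocyte differentiation list shifted upward with 0 of 19 members called and 1 risen adjusted over the list alone (median 0.17; list adjusted p = 0.000683, adjusted p = 0.27 with an estimated correlation, and 0.0533 without control replicate 2). By fry the hypoxia, immediate early and enterocyte lists did not pass with EAV9 (adjusted p = 0.0888, 0.277 and 0.155). Of 21 MAP kinase feedback genes 3 rose and 1 fell (5 and 4 adjusted over the list alone; list adjusted p = 0.399), with a median of −0.12 against a mean of 0.02; GADD45B rose by 1.63 ± 0.21 and DUSP2 was at least 2.19-fold lower.

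In total 195 genes changed with EAV9, 37 higher and 158 lower, against 1181 at an unadjusted p under 0.05. Of the 195, 132 changed at least 2-fold, and the groups did not overlap for 13.5% of all genes (chance 10% for unpaired arrays). The count was 671 with the replicate block (130 higher, 541 lower), and 20 when only the 6 arrays of the 2 groups were fitted; median centring gave 51 higher and 120 lower (29.8% higher, against 19.0%). Without control replicate 1, 2 or 3 the count was 115, 46 or 128, and without EAV9 replicate 1, 2 or 3 it was 55, 122 or 66.

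S1400 compared directly with EAV9 addresses what flagellated bacteria add to aflagellated ones. The genes higher with S1400 included chemokines, NF-kB feedback genes and immediate early genes. CXCL1 and CCL20, each above 4 on 1 EAV9 array, were higher by 9.93 and 8.87 with values below 4 set to 4, CXCL3 by 8.43 ± 0.49, and CXCL8 by at least 7.06. TNF, dim with EAV9, was at least 6.13-fold higher (4.88 ± 0.27). MIR146A and HCAR3, also above 4 on 1 EAV9 array each, were higher by 5.46 and 3.83 on the same basis. CXCL2 was higher by 7.88 ± 0.43, IRF1 by 5.72 ± 0.30, NFKBIA by 5.58 ± 0.31, ACKR3 by 5.05 ± 0.59 and TNFAIP3 by 4.30 ± 0.21, and NFKBID was at least 14.6-fold higher. Of 80 genes changed, 79 were higher with S1400 and 1 was lower, GAREM2, an adaptor of growth factor signalling (−0.96 ± 0.17, adjusted p = 0.0218). GAREM2 was not called without S1400 replicate 1, 2 or 3 (adjusted p = 0.0605, 0.145 and 0.0555), without EAV9 replicate 2 or 3 (0.119 and 0.0759) or with only the 6 arrays (0.12), and NFKBID was not called with only the 6 arrays (0.084).

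Of 27 immediate early genes 14 were higher with S1400 than with EAV9 and 0 lower (19 and 0 adjusted over the list alone; list adjusted p = 1.28e-45), including JUN (2.71 ± 0.15), JUNB (2.90 ± 0.29), FOS (2.20 ± 0.34) and KLF10 (1.95 ± 0.14); EGR1 differed by 1.10 ± 0.44 (adjusted p = 1). The call of FOS ended without S1400 replicate 1 (adjusted p = 0.0538), without EAV9 replicate 1 or 3 (0.0526 and 0.0514) and with only the 6 arrays (0.0609). Of 17 chemokines and cytokines 7 were higher and 0 lower (10 and 0 adjusted over the list alone; list adjusted p = 1.5e-36). Of 25 NF-kB feedback genes and targets 9 were higher and 0 lower (11 and 0 adjusted over the list alone; list adjusted p = 1.06e-29), with IER3 at 4.24 ± 0.31. Of 21 MAP kinase feedback genes 6 were higher and 0 lower (9 and 0 adjusted over the list alone; list adjusted p = 6.6e-20), with GADD45B at 3.39 ± 0.21 and DUSP1 at 2.80 ± 0.20. Among 23 apoptosis regulators PMAIP1 (3.97 ± 0.42) and CFLAR (0.80 ± 0.15) were higher and 0 were lower, the same numbers adjusted over the list alone (list adjusted p = 0.00786), with a list median of −0.02 against a mean of 0.26. The 12 tested probe sets of CFLAR ranged from −0.37 to 1.54 and 6 had the opposite sign, so its direction is uncertain. The list was not tested without PMAIP1. With an estimated correlation these 5 lists had adjusted p of 0.00025, 0.00025, 0.000988, 0.00112 and 0.0345. The 13 heat shock proteins shifted upward with 0 called, also adjusted over the list alone (median 0.23; list adjusted p = 0.0119, adjusted p = 0.314 with an estimated correlation, and 0.213 or 0.156 without S1400 replicate 1 or EAV9 replicate 3). Of 15 interferon-stimulated genes 1, ISG15 (1.95 ± 0.31), was higher, also adjusted over the list alone (list adjusted p = 0.0259, adjusted p = 0.314 with an estimated correlation, and 0.129 or 0.157 without S1400 replicate 3 or EAV9 replicate 1). Neither the heat shock nor the interferon-stimulated list passed by fry (adjusted p = 0.444 for each).

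The 80 genes compare with 472 at an unadjusted p under 0.05 and 76 changed at least 2-fold. The groups did not overlap for 7.10% of all genes, where chance gives 10% for unpaired arrays. As the replicate numbers pair the arrays, 7.10% cannot be read as below chance. With array weights 642 genes changed, 259 higher and 383 lower, and with only the 6 arrays of the 2 groups 44 did.

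**Figure D2:**
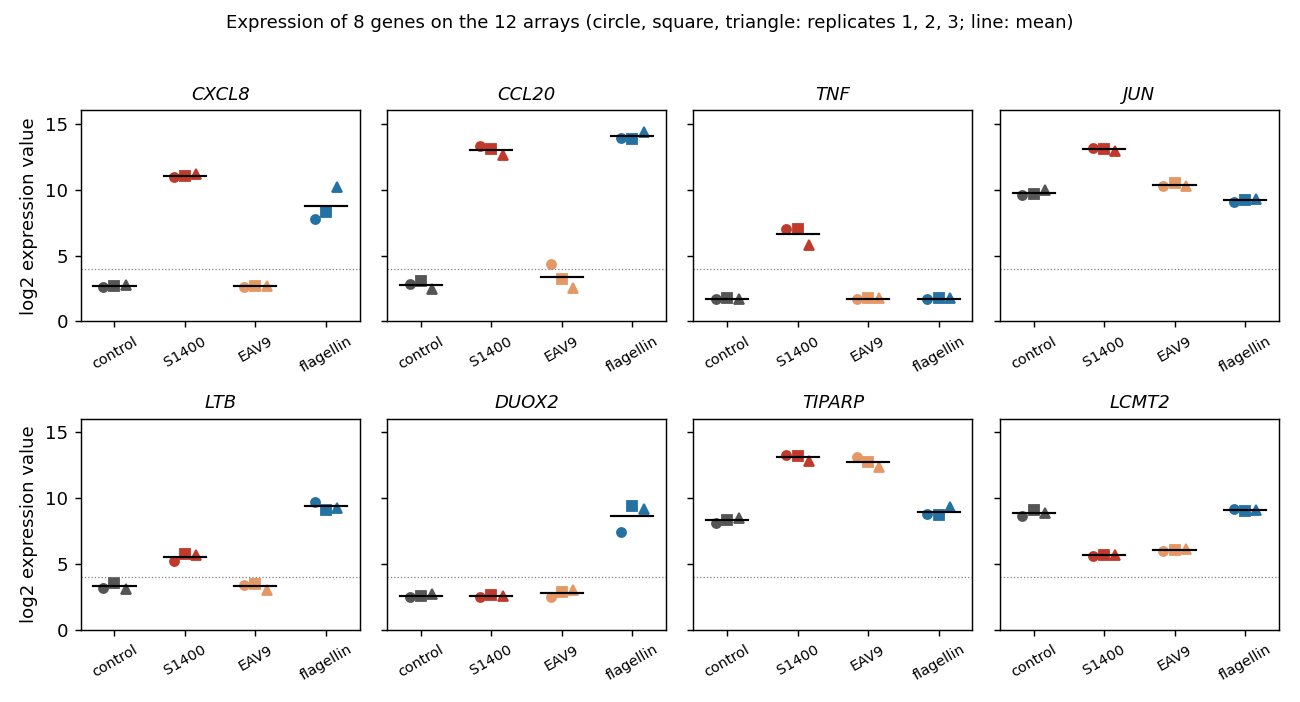
Log2 level of 8 genes on each of the 12 arrays by group. Circles, squares and triangles are replicates 1, 2 and 3, the line is the group mean and the dotted line marks a log2 level of 4. CXCL8 stood at a mean of 11.05 with S1400 and 8.75 with flagellin, against 2.66 with EAV9 and 2.70 in control cells, while TIPARP stood at 13.07 with S1400 and 12.72 with EAV9, against 8.93 with flagellin.

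Recombinant flagellin, compared with medium alone, shows what the protein does without bacteria. CCL20 was at least 1050.5-fold higher (11.25 ± 0.39), CXCL1 at least 141-fold (8.12 ± 0.32) and CXCL8 at least 27.0-fold (6.06 ± 0.46). CXCL10, a chemokine for T cells, rose at least 28.2-fold, and DUOX2, an epithelial oxidase that makes hydrogen peroxide, at least 24.99-fold. MIR146A rose at least 134-fold and the acute-phase protease inhibitor SERPINA3 at least 15.9-fold. OLR1, a scavenger receptor for oxidised lipoprotein, rose by 6.88 ± 0.27 (118-fold), ABTB2 by 6.40 ± 0.24, CXCL3 by 6.24 ± 0.49 and CXCL2 by 5.30 ± 0.43. LTB, a cytokine of the TNF family, rose at least 41.0-fold on the probe set used, while its other probe set changed by −0.70.

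Of 25 NF-kB feedback genes and targets 20 rose with flagellin and 0 fell (23 and 0 adjusted over the list alone; list adjusted p = 1.39e-29). TNFAIP3 rose by 3.41 ± 0.21, NFKBIA by 3.05 ± 0.31, and SOD2, the mitochondrial superoxide dismutase, by 3.46 ± 0.19; the surface receptors CD83 and TNFRSF9 rose at least 4.39-fold and 3.44-fold. Of 17 chemokines and cytokines 10 rose and 0 fell (13 and 0 adjusted over the list alone; list adjusted p = 3.06e-21). Of 23 apoptosis regulators 5 rose and 0 fell (8 and 1 adjusted over the list alone; list adjusted p = 0.00018), among them CFLAR (2.12 ± 0.15) and the death receptor TNFRSF10B (2.83-fold). Of 21 MAP kinase feedback genes 6 rose and 0 fell (9 and 0 adjusted over the list alone; list adjusted p = 3.67e-06), with PHLDA1 at 2.38 ± 0.13. With an estimated correlation these 4 lists had adjusted p of 0.00142, 0.00142, 0.0123 and 0.046. The list of flagellin and microbe sensing, given next, had adjusted p = 0.00247 by fry. Among 17 genes of flagellin and microbe sensing, 3 rose and 0 fell (3 and 1 adjusted over the list alone; list adjusted p = 0.0522): the kinase IRAK2 (3.66 ± 0.23) and the adaptors TRAF6 (0.99 ± 0.17) and TICAM1 (1.98 ± 0.44).

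Of 13 epithelial antimicrobial defence genes 3 rose and 0 fell (4 and 0 adjusted over the list alone; list adjusted p = 4.96e-05, and adjusted p = 0.0862 with an estimated correlation). They were DUOX2, the elastase inhibitor PI3 (2.87 ± 0.27) and the siderophore-binding LCN2, at least 1.71-fold higher. By fry this list had adjusted p = 0.000759. The immediate early, junction, sterol synthesis, interferon-stimulated and cell cycle lists below did not pass by fry (adjusted p of 0.0655, 0.143, 0.133, 0.06 and 0.177). Of 27 immediate early genes 5 rose and 3 fell (6 and 3 adjusted over the list alone; list adjusted p = 0.00988, and adjusted p = 0.316 with an estimated correlation). SGK1 rose by 2.45 ± 0.28 and ATF3 by 2.44 ± 0.40, and JUN changed by −0.57 ± 0.15 (adjusted p = 0.0479, but 0.0527 after median centring, 0.593 with its probe sets averaged and 0.0537 to 0.144 with any 1 of the 12 arrays left out). FOS differed by −0.88 ± 0.34 (adjusted p = 0.165) and EGR1 by 0.03 ± 0.44 (adjusted p = 0.985). Of 23 junction genes 4 rose and 1 fell, the same numbers adjusted over the list alone (list adjusted p = 0.00509, and adjusted p = 0.367 with an estimated correlation); CLDN12 rose by 0.95 ± 0.18, TJP1, the scaffold ZO-1, by 0.91 ± 0.22 and CLDN4 by 0.73 ± 0.17, and the desmosomal PKP2 changed by −0.96 ± 0.19. The 14 sterol synthesis genes shifted upward with 1 called, also adjusted over the list alone (SC5D, 0.48 ± 0.12, while its other probe set changed by −0.34; list adjusted p = 0.00988, and adjusted p = 0.367 with an estimated correlation). Of 15 interferon-stimulated genes 1 rose, also adjusted over the list alone (ISG20, 1.60 ± 0.25; list adjusted p = 0.00988, adjusted p = 0.294 with an estimated correlation, and 0.0636 without control replicate 1). The 25 cell cycle genes shifted downward with 0 called, also adjusted over the list alone (median −0.33; list adjusted p = 0.00988, adjusted p = 0.485 with an estimated correlation, and 0.0503 or 0.145 without control replicate 2 or flagellin replicate 2).

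The largest falls with flagellin were smaller than its largest rises. The transporter pseudogene ABCC6P1 changed by −2.52 ± 0.32 and FGD3, an exchange factor for CDC42, by −2.25 ± 0.19. ZNRF3, a ubiquitin ligase that removes Wnt receptors, changed by −1.99 ± 0.31, JMY, above 4 on 1 flagellin array, by −2.04 ± 0.43 (−1.63 with values below 4 set to 4), and PSRC1 was at least 2.30-fold lower. The transcripts CKMT2-AS1, CUTALP and LIPT2-AS1 changed by −2.03, −1.96 and −1.92. CUTALP was not called with no filter on dim genes (adjusted p = 0.0854), with the actin covariate (0.0579), or without any 1 of 7 arrays (0.0537 to 0.137). JMY was not called with no filter (0.0509), or without replicate 1 or 2 of control (0.072 and 0.0517) or of flagellin (0.0716 and 0.051). With only the 6 arrays, PSRC1, CKMT2-AS1 and CUTALP were not called (0.0573, 0.0747 and 0.114).

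In total 640 genes changed with flagellin, 393 higher and 247 lower, against 2201 at an unadjusted p under 0.05. Of the 640, 374 changed at least 2-fold, and the groups did not overlap for 22.8% of all genes (chance 10% for unpaired arrays). The replicate block gave 1915 genes (959 higher, 956 lower), and quantile normalisation 318 higher and 304 lower (51.1% higher, against 61.4%). Without control replicate 1 or 2 the count was 426 or 399, and without flagellin replicate 1 or 2 it was 408 or 339.

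The 393 genes raised by flagellin were then read in S1400 against EAV9, which shares no array with flagellin against control. CCL20, CXCL1, CXCL8, NFKBIA and TNFAIP3 were among the 35 that were also higher with S1400 than with EAV9, where independent lists would share 2.85. Of all 393, 209 (53.2%) had a positive change, with a median of 0.02 and a mean of 0.36. As a set the 393 genes were higher with S1400 (camera p = 2.5e-13, and p = 0.0273 with an estimated correlation; fry p = 0.0119). With the replicate block, or without EAV9 replicate 3, the median was −0.01 or −0.0027, with only the 6 arrays it was 0.10 (124 of 191 positive), and without the arrays numbered 2 it was 0.21 (64 of 88); the test pointed upward each time. Across all 10904 genes the changes correlated at a Pearson r of 0.313 and a Spearman rho of 0.0713; genes are not independent replicates. Of the 247 genes lowered by flagellin, 0 were lower with S1400 than with EAV9 by the limma fit, against 1 lower gene in all, and 187 (75.7%) had the same sign. The median change of all genes in S1400 against EAV9 was −0.04, so negative changes were common among them. The shares of 53.2% and 75.7% were not set against the share over all genes.

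**Figure D3:**
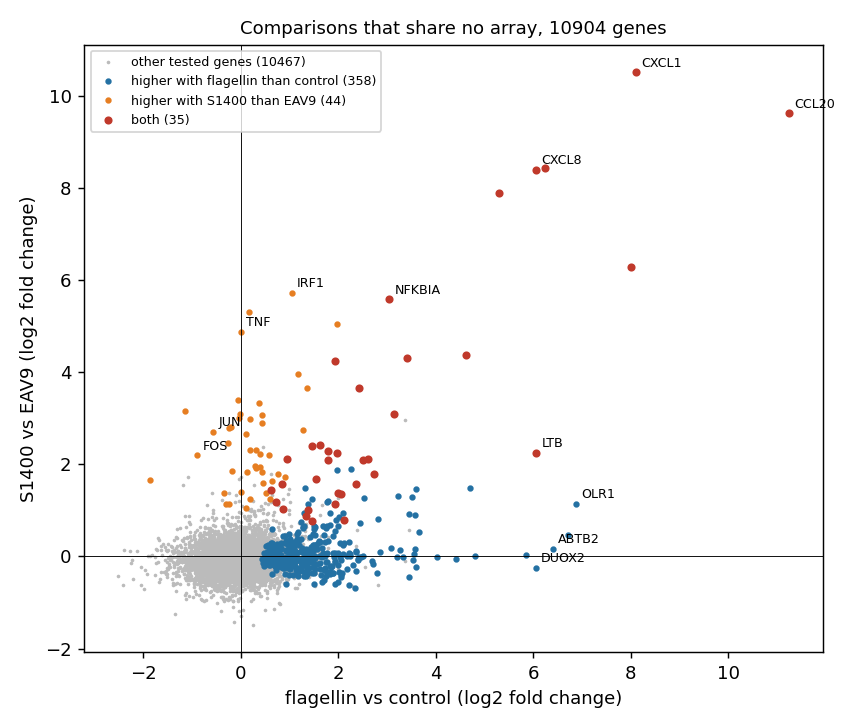
Log2 change of flagellin against control (horizontal) and of S1400 against EAV9 (vertical) for 10904 genes. Of these, 358 were higher in the flagellin comparison alone, 44 in the strain comparison alone and 35 in both; 10467 are drawn as others.

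S1400 and flagellin, compared directly, differed in both directions. Higher with S1400 were JUN (3.86 ± 0.15), FOS (3.96 ± 0.34), GADD45B (5.07 ± 0.21), IRF1 (4.60 ± 0.30) and TNF, at least 6.13-fold. SMAD7, an inhibitor of TGF-beta signalling, was higher by 4.94 ± 0.29 (4.64 with values below 4 set to 4, as 1 flagellin array exceeded 4), H2BC21 by 4.35 ± 0.43, TIPARP by 4.15 ± 0.23, ADM by 3.88 ± 0.59, DDIT4 by 3.77 ± 0.34 and the gluconeogenic enzyme PCK1 by 3.85 ± 0.47, and NFKBID was at least 14.6-fold higher. Lower with S1400 were ZC3H12C (−6.74 ± 0.56, or −6.29 with values below 4 set to 4, as 1 S1400 array exceeded 4), ABTB2 (−6.49 ± 0.24) and OLR1 (−5.45 ± 0.27). CXCL10 was at least 28.2-fold lower with S1400, DUOX2 at least 24.99-fold, SERPINA3 at least 15.9-fold, ANKRD33B at least 7.14-fold and SPRY4-IT1 at least 6.02-fold. CXCL8 was higher with S1400 by 2.30 ± 0.46 and CXCL1 by 2.84 ± 0.32, while CCL20 differed by −1.04 ± 0.39 (adjusted p = 0.105). With only the 6 arrays CXCL8 was not called (adjusted p = 0.0583) and CCL20 was (0.0413). CCL20 also passed without EAV9 replicate 1 or 3 (0.0238 and 0.049) and with array weights (0.0371).

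Members of the same list went opposite ways. By fry the NF-kB, immediate early, hypoxia, antimicrobial and sensing lists below had adjusted p of 0.00286, 3.26e-05, 0.0117, 0.00286 and 0.000268. The chemokine and cell cycle lists did not pass by fry (0.152 and 0.267). Of 25 NF-kB feedback genes and targets 6 were higher with S1400 and 12 lower (6 and 14 adjusted over the list alone; list adjusted p = 0.0438, adjusted p = 0.523 with an estimated correlation, 0.0993 without S1400 replicate 3, and 0.594 when only genes with log2 above 6 on 3 arrays were tested); NFKBIA was higher by 2.51 ± 0.31, EFNA1 by 2.57 ± 0.19 and TNFAIP3 by 1.23 ± 0.21, and CD83 and TNFRSF9 were at least 4.39-fold and 3.44-fold lower. Of 17 chemokines and cytokines 5 were higher and 5 lower (6 and 7 adjusted over the list alone; list adjusted p = 0.703), LTB among the lower (−3.81 ± 0.22, while its other probe set changed by 0.52). Of 27 immediate early genes 13 were higher and 2 lower (14 and 4 adjusted over the list alone; list adjusted p = 4.14e-09, and adjusted p = 0.103 with an estimated correlation), HES1 (2.40 ± 0.17) among the higher. Of 23 hypoxia and glycolysis genes 6 were higher and 1 lower (6 and 2 adjusted over the list alone; list adjusted p = 0.0438, adjusted p = 0.509 with an estimated correlation, 0.0603 with the replicate block, and 0.0692, 0.086 or 0.0531 without S1400 replicate 1 or flagellin replicate 1 or 3). The antimicrobial DUOX2, PI3 (−2.53 ± 0.27) and LCN2 were lower, 3 of 13 members with 0 higher, the same numbers adjusted over the list alone (list adjusted p = 0.0551, and 0.0454 with the replicate block). IRAK2 (−3.16 ± 0.23) and TRAF6 (−1.46 ± 0.17) were the 2 of 17 sensing genes that were lower, with 0 higher, the same numbers adjusted over the list alone (list adjusted p = 0.0438, adjusted p = 0.246 with an estimated correlation, and 0.0503 to 0.105 without control or EAV9 replicate 2, S1400 replicate 2 or 3, or flagellin replicate 1 or 3). Of 25 cell cycle genes BUB1 (1.93 ± 0.45) and TOP2A (0.87 ± 0.24) were higher and 0 lower (1 and 0 adjusted over the list alone; list adjusted p = 0.0438, adjusted p = 0.812 with an estimated correlation, 0.0623 with the replicate block, and 0.22, 0.165 or 0.0531 without S1400 replicate 1 or flagellin replicate 2 or 3).

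In total 1563 genes differed between S1400 and flagellin, 458 higher and 1105 lower with S1400. Of the 1563, 843 differed at least 2-fold, and the groups did not overlap for 30.2% of all genes (chance 10% for unpaired arrays). Of the 393 genes raised by flagellin over control, 306 were lower with S1400 than with flagellin and 14 higher (median −1.15), a comparison that shares the flagellin arrays with the choice of the genes. The replicate block gave 3159 genes (1122 higher, 2037 lower), and median centring 657 higher and 928 lower (41.5% higher, against 29.3%); without S1400 replicate 2 or flagellin replicate 2 the count was 951 or 977.

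Flagellin compared with EAV9 sets the protein against bacteria taken as lacking it. CCL20, ZC3H12C, CXCL1 and MIR146A each exceeded 4 on 1 EAV9 array. With values below 4 set to 4 they were higher with flagellin by 9.91, 6.45 and 7.09 on the log2 scale and 128-fold, in that order. ABTB2 was higher by 6.65 ± 0.24 and OLR1 by 6.59 ± 0.27. CXCL8 was at least 27.0-fold higher, LTB at least 41.0-fold on the probe set used (its other probe set changed by −0.79), and the transcription factor ETS1 higher by 5.59 ± 0.53. Lower with flagellin were H2BC21 (−4.19 ± 0.43), TIPARP (−3.79 ± 0.23), ADM (−3.37 ± 0.59), SMAD7 (−3.29 ± 0.29, or −2.99 with values below 4 set to 4, as 1 flagellin array exceeded 4), AMACR (−2.98 ± 0.28) and the transcription factor MAF (−2.64 ± 0.25), and PDCD4 was at least 3.76-fold lower. Of 25 NF-kB feedback genes and targets 21 were higher and 1 lower (24 and 1 adjusted over the list alone; list adjusted p = 1.29e-20), and of 17 chemokines and cytokines 12 were higher and 0 lower (13 and 0 adjusted over the list alone; list adjusted p = 1.01e-15). Both lists had adjusted p = 0.00489 with an estimated correlation. At the preset correlation the MAP kinase feedback, antimicrobial, apoptosis, sensing and heat shock lists also shifted upward with flagellin. The cell cycle, hypoxia and enterocyte lists shifted downward (list adjusted p of 0.00394 to 0.0403 for all of these). None of these passed with an estimated correlation (0.0666 to 0.542), and by fry all but cell cycle (0.205) did. Some calls ended in fits with 1 array left out. The adjusted p was then 0.0705 to 0.102 for heat shock, 0.0586 for sensing and 0.0672 or 0.0677 for hypoxia. It was 0.0505 to 0.109 for the enterocyte list and 0.129 or 0.144 for cell cycle. The heat shock call also ended after quantile normalisation (0.0855). Of 27 immediate early genes 7 were higher and 5 lower (10 and 6 adjusted over the list alone; list adjusted p = 0.531), JUN (−1.15 ± 0.15) and FOS (−1.77 ± 0.34) among the lower.

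In total 1296 genes differed between flagellin and EAV9, 892 higher and 404 lower with flagellin, 688 of them at least 2-fold. The groups did not overlap for 28.0% of all genes (chance 10% for unpaired arrays). The replicate block gave 2893 genes (1671 higher, 1222 lower); without EAV9 replicate 1 or flagellin replicate 2 the count was 831 or 852.

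Genes changed by EAV9 changed likewise between S1400 and flagellin, a comparison that shares no array with EAV9 against control. Of the 37 genes higher with EAV9, 31 were also higher with S1400 than with flagellin, where independent lists would share 1.55, TIPARP, H2BC21 and DDIT4 among them. Of the 158 lower genes 128 were also lower, against 16.01 for independent lists. Across 10904 genes the changes correlated at a Pearson r of 0.505 and a Spearman rho of 0.396.

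The remaining lists showed few calls against control. Of 19 genes of unfolded protein and amino acid stress, 1 rose with S1400 (PPP1R15A, 3.14 ± 0.33; list adjusted p = 0.518), 0 were called with EAV9 (list adjusted p = 0.735) and 1 rose with flagellin (SLC7A11, 1.83 ± 0.46; list adjusted p = 0.131), the same numbers adjusted over the list alone. Of 13 heat shock proteins 0 were called with S1400 (list adjusted p = 0.602), 1 fell with EAV9 (DNAJB1, −1.62 ± 0.34; list adjusted p = 0.437) and 0 were called with flagellin (list adjusted p = 0.131, and 0.0324 with the replicate block), the same numbers adjusted over the list alone. Of 15 genes of oxidative stress and metallothioneins 1 rose with flagellin (TXNRD1, 0.80 ± 0.17; list adjusted p = 0.843), and 1 rose and 1 fell adjusted over the list alone; with S1400 and EAV9 0 were called either way (list adjusted p = 0.635 and 0.682). Of 8 fibroblast and endothelial markers 0 were called against control in any group, also adjusted over the list alone (list adjusted p of 0.679, 0.682 and 0.941 for S1400, EAV9 and flagellin). Of 6 goblet, Paneth and enteroendocrine markers 0 were called, also adjusted over the list alone (list adjusted p of 0.19, 0.495 and 0.941), and AGR2, which Caco-2 cells express, stood at 15.52 in control cells and 15.54 to 15.62 in the others. Of 21 leukocyte markers only 2 were tested, LYZ and CD74, too few for a list test, and neither was called; LYZ is also on the Paneth list.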

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

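The differences between the changes caused by bacteria and by flagellin were tested as planned comparisons; TNFSF15 and ZC3H12D, and the count of probe sets without a single gene name, were singled out after the values were seen.

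Genes that moved in opposite directions drew attention first, since S1400 and flagellin both raised chemokines. In comparisons against control, 19 genes were called in opposite directions with S1400 and flagellin, and 10 with EAV9 and flagellin. ZC3H12C, of the RNA-degrading ZC3H12 family, changed by −3.16 with S1400, −4.05 with EAV9 and 3.58 with flagellin; the difference was −6.74 for S1400 minus flagellin and 7.63 for flagellin minus EAV9 (adjusted p = 4.35e-05 and 2.12e-05). It exceeded 4 on 1 array of each strain, and with values below 4 set to 4 its changes were −2.71 with S1400 and −2.87 with EAV9, and the differences −6.29 and 6.45. SMAD7, an inhibitor of TGF-beta signalling, changed by 3.09 with S1400, 1.44 with EAV9 and −1.85 with flagellin, with differences of 4.94 and −3.29 in the same order (adjusted p = 3.93e-06 and 7.32e-05), or 4.64 and −2.99 with values below 4 set to 4, as 1 flagellin array exceeded 4; its change with flagellin was then −1.55. TNFSF15, a cytokine of the TNF family, changed by −1.76, −2.05 and 2.11 with S1400, EAV9 and flagellin in the fit, with differences of −3.88 and 4.16. It exceeded 4 on 1 S1400 array and was dim with EAV9; with values below 4 set to 4 it fell by 1.32 with S1400 and by at least 1.36 with EAV9, and the differences were −3.44 and at least 3.48. ZC3H12D, a relative of ZC3H12C, changed by −1.61 with EAV9 and 2.05 with flagellin, a difference of 3.67 for flagellin minus EAV9. JUN changed by 3.29 with S1400 and −0.57 with flagellin, a difference of 3.86; its fall with flagellin lay close to the threshold (adjusted p = 0.0479) and was not called after median centring (0.0527) or with any 1 of the 12 arrays left out (0.0537 to 0.144).

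Probe sets with several gene names or none also changed. Of 2900 tested, 209 changed with S1400 (144 higher, 65 lower), 76 with EAV9 (49 higher, 27 lower) and 127 with flagellin (77 higher, 50 lower), each against control. Of all 22512 probe sets in the same fit, 1331, 402 and 970 changed in that order. With S1400 and EAV9 the rises outnumbered the falls among the 2900, unlike among the genes. They are given as counts, since no single gene can be named for them.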

How the results depend on the processing

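The alternatives chosen after the data were seen were rounding to 3 digits, the actin difference as a covariate and leaving out the 4 arrays numbered 2; the others were planned. None of the called results for the fixed genes and those with the largest changes reversed its direction where 1 value per gene was fitted, and none of the called lists did in the alternatives run on lists (the estimated correlation, fry, the replicate block, quantile normalisation, the stricter filter and arrays left out). With every probe set tested on its own, called genes had a probe set that changed the other way: LTB with flagellin (−0.70 against control, −0.79 against EAV9) and BCL2L11 with S1400 and EAV9 (−1.40 and −1.19 against control), at an unadjusted p under 0.05. The balance of the counts did: S1400 against control had 71 higher and 42 lower (62.8% higher, against 29.7%) without the arrays numbered 2, so the predominance of falls did not hold there, and S1400 against EAV9 had 259 higher and 383 lower (40.3% higher, against 98.8%) with array weights. EAV9 against control had 10 higher and 10 lower with only the 6 arrays, and 1 and 1 without the arrays numbered 2. The median of the flagellin-raised genes in S1400 against EAV9, near 0, ranged from −0.0027 to 0.08 with 1 array left out, and was −0.01 with the replicate block, 0.10 with only the 6 arrays and 0.21 without the arrays numbered 2. Counts below are for S1400, EAV9 and flagellin against control, then S1400 against EAV9, S1400 against flagellin and flagellin against EAV9; where a value is absent, it lay within 1.5 times the reported count. Every probe set tested on its own gave 1331, 402, 970, 153, 2805 and 2176 probe sets, and 2551 in the F test, with more features tested. Of these, 45.7% were higher for S1400 against control (against 29.7%) and 41.5% for EAV9 against control (against 19.0%). With the probe sets of a gene averaged, these shares were 39.4% and 29.2%. The predominance of falls was thus smaller in both settings. Only the 6 arrays of the groups compared gave 367, 20, 261, 44, 1036 and 833, with fewer arrays to estimate the spread. The replicate block gave 1587, 671 and 1915 against control, 3159 for S1400 against flagellin, 2893 for flagellin against EAV9 and 3384 in the F test, and kept every gene called without it; it ended 3 list calls, brought 2 lists and JUN with EAV9 past the threshold, and changed no other call of a named gene or list. S1400 against EAV9 rose to 118 with it. Array weights gave 1568 for S1400 against control, 642 for S1400 against EAV9, 3660 for S1400 against flagellin, 2035 for flagellin against EAV9 and 3454 in the F test; the cause was not tested. A 2-fold minimum left 397 for S1400 against control, 374 for flagellin against control, 843 for S1400 against flagellin and 688 for flagellin against EAV9. Without the 4 arrays numbered 2, which leaves 2 arrays per group, the counts were 113, 2, 96, 29, 435 and 388, and 279 in the F test; flagellin against control had 88 higher and 8 lower (91.7% higher, against 61.4%).

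With 1 array left out the ranges were 309 to 651, 46 to 173, 339 to 688, 61 to 81, 951 to 1634 and 831 to 1293, and 955 to 1432 in the F test. The count for S1400 against control moved by over 1.5 times without control replicate 2 (368) or S1400 replicate 2 (309). For EAV9 it did so without control replicate 1 (115), 2 (46) or 3 (128), or EAV9 replicate 1 (55), 2 (122) or 3 (66). For flagellin it did so without control replicate 1 (426) or 2 (399), or flagellin replicate 1 (408) or 2 (339). S1400 against flagellin fell without S1400 replicate 2 (951) or flagellin replicate 2 (977), and flagellin against EAV9 without EAV9 replicate 1 (831) or flagellin replicate 2 (852).

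Of 143 results for the fixed genes and those with the largest changes, 143 kept their side of the threshold with quantile normalisation, 141 with median centring, 138 with no filter, 140 with the actin covariate, 142 with rounding, 125 with only the 6 arrays and 104 without the arrays numbered 2. Of 42 list calls among 108 tests, 15 remained with an estimated correlation, 29 with fry and 31 without the arrays numbered 2. With 1 array left out in turn, 60 of 1716 such gene results and 35 of 504 list results lost their call, and 2 gene results gained one. The other list members named were not followed through the alternatives. The rule that log2 must exceed 4 leaves genes such as TLR5 untested, and calls on small changes are limited by 3 arrays per group.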

Other observations

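Both gene families were chosen after the results were seen, and so were all tests on them. Their Fisher p and percentiles therefore describe these data and are not independent support. The tests below on the genes raised by flagellin were also chosen then, including the choice to hold arrays out. The immediate early list and the share of those genes higher with S1400 than with EAV9 come from planned comparisons. Their use to judge an earlier stage was chosen afterwards. The other splits of the arrays were planned; their second draw was added afterwards.

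Both strains raised histone genes, which flagellin did not. Of 18 replication-dependent histone genes, 9 rose and 1 fell with S1400 (0.320 rises expected from all genes; Fisher's exact adjusted p = 7.54e-11) and 6 rose and 0 fell with EAV9 (0.0611 expected; adjusted p = 1.08e-10). With flagellin 0 rose and 0 fell in the limma fit, and 10 were higher with S1400 than with flagellin (Fisher's exact adjusted p = 2.01e-09). The family medians were 1.21, 1.18 and −0.12. H2BC21 rose by 4.37 with S1400, H1-2 by 2.58 and H4C11 by 2.25, while H3C6 changed by −1.95; with EAV9, H2BC21, H1-2 and H4C11 rose by 4.21, 1.93 and 1.67. The signs of the family medians were the same after quantile normalisation and median centring, but H3C6 was no longer called with S1400 after centring. Histone probe sets may hybridise to several family members, so the number of separate genes behind these calls is uncertain. Without control array 2 the numbers were 7 risen and 0 fallen with S1400, and 3 and 0 with EAV9, with medians of 1.09 and 1.15. Without the 4 arrays numbered 2, which leaves 2 per group, 2 rose with S1400 and 0 with EAV9 in the limma fit, with medians of 1.10 and 1.13. With the actin difference as a covariate, both strains together stood 1.11 above control (SE 0.18, against 1.04 without), or 0.95 (SE 0.17) without control array 2. This argues against RNA quality, as far as actin reads it, as the whole cause. The GAPDH difference was not tried as a covariate. The median lay at percentile 100 of 10000 gene sets matched on mean level, whose central range was −0.20 to 0.08. Genes of that level thus did not rise as far in general. As the family was chosen after the results were seen, the percentile does not test chance. Since poly(A) RNA was labelled and most histone transcripts lack such tails, a change in tail processing stays open and was not tested, as does a change in histone gene transcription.

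Zinc finger genes fell with both strains. Of 284 genes named ZNF or ZFP with a number, 38 fell and 2 rose with S1400 (11.96 falls expected; Fisher's exact adjusted p = 1.21e-09), and 21 fell and 1 rose with EAV9 (4.12 expected; adjusted p = 2.26e-09). With flagellin 7 fell and 6 rose, and the family medians were −0.39, −0.28 and −0.06. S1400 against flagellin, which uses no control array, gave 64 lower and 9 higher (28.8 falls expected; adjusted p = 2.26e-09), and flagellin against EAV9 gave 43 higher and 5 lower (23.2 rises expected; adjusted p = 0.000201). The signs of these medians were the same after quantile normalisation and median centring, where the S1400 median was −0.27 against 0.06 for all genes. The actin difference, a sign of RNA quality, was 1.13 ± 0.45 in control cells and 0.97 ± 0.32 and 0.93 ± 0.21 with S1400 and EAV9 (SD, n = 3). Control array 2 had the highest, 1.6, and stood apart for these genes, with a median deviation of 0.36 against 0.05 and 0.11 on the other control arrays. Without it 20 fell with S1400 and 6 with EAV9, with medians of −0.32 and −0.20, and of all genes 207 were lower with S1400 rather than 459, so the number of falls rests in part on this array. S1400 against flagellin then gave 66 lower and 8 higher. Without the 4 arrays numbered 2 the falls numbered 5 with S1400 and 0 with EAV9 in the limma fit, with medians of −0.35 and −0.27, and S1400 against flagellin gave 18 lower and 1 higher. With the actin difference as a covariate, both strains together stood at −0.27 against control (SE 0.04, against −0.31 without), and at −0.23 (SE 0.03) without control array 2. These values argue against RNA quality, as far as actin reads it, as the whole cause. The median of −0.35 lay at percentile 0 of 10000 gene sets matched on mean level, whose central range was −0.10 to −0.02, against the explanation that dim genes move this way whatever they encode. Of the genes called with EAV9, 97.9% had the same sign in S1400 against flagellin, against the control arrays alone being out of place. Faster loss of short-lived transcripts, or reduced transcription, in cells with bacteria of either strain may account for the falls; neither was tested.

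Genes raised by flagellin were mostly lower with S1400 than with flagellin, 306 of 393, although CXCL1 and CXCL8 were higher with S1400 by 2.84 and 2.30. Against control, S1400 raised 53 of the 393 and lowered 14, and EAV9 raised 4 and lowered 7. The flagellin arrays enter both the choice of these genes and the comparison, so the genes were chosen again without each flagellin array in turn, and S1400 was read against that array. The medians were −1.14, −1.56 and −1.02, each at percentile 0 of 10000 gene sets matched on mean level, whose central ranges lay between −0.12 and 0.08. This argues against a shift left by the normalisation in genes of that level. Whether bacteria of either strain slightly lower these genes from their resting level stays open. The control arrays are likewise shared with EAV9 against control. With each control array held out in turn, the medians for EAV9 were 0.01, −0.09 and −0.08, at percentiles 16.9, 81.3 and 0.45 of matched sets. The answer thus depends on the control array. These medians are small beside the −1.14, −1.56 and −1.02 of S1400 against flagellin. That argues against a lowering from rest shared by both strains as the account of that difference. An earlier stage of the same response stays a candidate explanation. The immediate early list was higher with S1400 than with flagellin under the preset correlation, by fry (adjusted p = 3.26e-05) and with the replicate block (3.1e-07). It did not pass with an estimated correlation (adjusted p = 0.103). Of the 393 genes, 53.2% were higher with S1400 than with EAV9. That share was 49.2% (472 of 959) with the replicate block and 49.5% without EAV9 replicate 3, but 72.7% (64 of 88) without the arrays numbered 2, 64.9% with only the 6 arrays of the groups compared and 64.0% without EAV9 replicate 2, each on the genes raised by flagellin under that setting. The share therefore decides neither way. A smaller amount of flagellin reaching the cells from the bacteria, or bacteria that hold back the induction of these genes, also stays open and could not be tested with 1 time and 1 dose.

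Other splits of the arrays were counted for each comparison. Of 10 splits of each set of 6 arrays, 1 gave as many genes as observed, the real one, and 10 are too few for a share under 0.05. The real counts were 653, 195, 640, 80, 1563 and 1296 for S1400, EAV9 and flagellin against control, S1400 against EAV9, S1400 against flagellin and flagellin against EAV9, and the highest other counts were 0, 1, 1, 0, 0 and 0. Among the 4 splits that part all 3 replicate pairs, the others gave 0 in each comparison. For the F test, 1 of 100 splits of the 12 arrays, the real one, gave as many genes as the real 1432. That share is under 0.05, which argues against chance without excluding it. The highest other count was 1340, from a split that kept 1 group whole, and the 88 drawn splits that kept none whole gave at most 7. A second draw of 99 splits beside the real one gave 2 of 100, with 1872 genes in a split that kept 1 group whole and at most 1166 in the 91 that kept none whole, so these highest counts depend on the draw. Shuffled within replicate numbers, 1 of 100 did in either draw; the highest other counts were 1162 and 408, with 2 groups kept whole, against at most 245 and 238 in the 66 and 80 drawn splits that kept none whole.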
